A study of Daphnia magna with 12 samples.

How the data were processed

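Gene expression was measured in whole female Daphnia magna, the water flea, after 21 days in culture medium with or without tris(2-butoxyethyl) phosphate (TBEP), an organophosphate ester used as a flame retardant. The 12 samples fell into 4 groups of 3 biological replicates: unexposed controls and TBEP at 14.7, 147 and 1470 µg/L. Each replicate was total RNA from a pool of 10 animals that entered the exposure as neonates, per the labels. Each RNA was labelled with Cy3 and hybridised alone to an Agilent array with 14338 probes, of which 870 were printed at 2 spots, and 536 control spots.

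The deposited scanner files give a linear intensity for every spot, and the authors extracted these with Agilent Feature Extraction 11.5.1.1, per the file headers. The main values were the processed signal, an intensity that the software had already corrected for background, per the file headers. The deposited spot flags (other columns of the same files) state whether a spot was well above background, saturated or an outlier, per the file headers. No probe spot was saturated on any array. The 28 spots marked as outliers were left out. The authors' deposited table of log2 values for the same arrays carried no statement of its scale. It was set against the scanner values: it matched quantile normalised log2 processed signals, centred on each probe's median over the arrays, with r between 0.998 and 1.00 per array. Its scale, centring and direction were thereby settled. Its column medians lay between -0.03 and 0.13. It served only as an alternative.

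The log2 processed signal of each array was set relative to the array's 75th percentile, and spots of one probe were averaged. A probe was tested where it was well above background on all 3 arrays of at least 1 group, which left 10040 probes (70.0%). Between 8925 and 11125 probes were well above background on an array. Groups were compared with limma 3.58.1 in R 4.3.3: a linear model of group means over all 12 arrays with moderated variances, two-sided tests, and Benjamini-Hochberg adjustment over the tested probes at a threshold of 0.05. The comparisons were each dose against control, a linear trend over the rank of the dose, an F test over the 4 groups, and the doses against each other. Where a probe was well above background on no array of a group, its fold is given as a lower bound against the lowest signal among probes well above background on each array. The groups, comparisons and alternatives were fixed before the data were examined. The difference of the 4 groups over all probes at once was tested with a permutation test of the pseudo-F of Euclidean distances between arrays, with 100000 permutations. That test was added after the data had been seen.

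The probes carry identifiers of the array design but no gene name, description or accession, and the gene table used here (assembly ASM2063170v1.1) has no column that matches them. No probe could therefore be tied to a gene. The gene lists and the rule for named genes that had been fixed beforehand could not be applied. In their place, at most 2 probes higher and 2 lower are named per comparison, those with the smallest p, a rule set after the files had been seen. The probes named in the closing part were chosen after their values were seen.

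The limma analysis was tested on simulated data with the real probes' means and spread. For 1470 µg/L against control, with 200 of 10040 probes changed, it called 38.5% of the probes changed 2-fold with 5 false calls, 84.5% of those changed 4-fold with 8 false calls, and 93.5% of those changed 16-fold with 11 false calls. The simulated values were drawn independently for each probe, with the same spread on every array. They held no array that stands apart and no probes that vary together, so these rates may not hold for the real arrays. They also had 200 probes changed at once, and the adjustment is stricter where fewer probes change, so isolated changes may be recovered less often. The number of arrays limits the precision of every comparison.

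The arrays came from 2 slides, told apart by the file headers. Slide 1 held replicates 1 and 2 of every group and slide 2 held replicate 3, so slide and group were balanced. On slide 2 each group had a single array, so only values, no tests, are given within that slide. Replicate numbers come from the labels, which do not say that a number marks a shared batch. Alternatives covered the background correction (normexp with an offset of 50, on the median signal because the scanner files give no mean signal). They also covered quantile and median normalization, the filter on dim probes, the replicate number and the slide as blocks, and slide 1 alone. Further ones were the variance model, array weights, the deposited log2 values, each pair of groups fitted alone and other dose scales. The last were a threshold of unadjusted p under 0.05 with a 1.5-fold minimum, and leaving out each array. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.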

Results

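The data set held 12 whole-animal expression profiles of Daphnia magna, with 3 pools of 10 females in each of 4 groups. It addressed which transcripts differed after 21 days of exposure to sublethal concentrations of TBEP. The concentrations rose in 10-fold steps from 14.7 to 1470 µg/L. On each array between 8925 and 11125 of the 14338 probes were well above background, and the 75th percentile of the signal lay between 172 and 261 intensity units.

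The 12 profiles were similar, and no division by dose was detected. Without replicate 1 at 14.7 µg/L, the correlation across probes between any pair of arrays was at least 0.955. Its median was 0.977 within groups and 0.979 between groups, where probes are not independent replicates. Replicate 1 at 14.7 µg/L stood apart, with a median correlation of 0.900 with the other arrays. The first principal component, with 49.6% of the variance, separated this array from the rest, and the second held 13.5%. Group membership accounted for 26.6% of the squared distances between arrays (pseudo-F 0.969, permutation test, p = 0.511). With labels permuted within slides the permutation p was 0.547, without replicate 1 at 14.7 µg/L it was 0.915, and without replicate 2 at that dose it was 0.065 (pseudo-F 1.58, 40.4% of the squared distances).

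**Figure D1:**
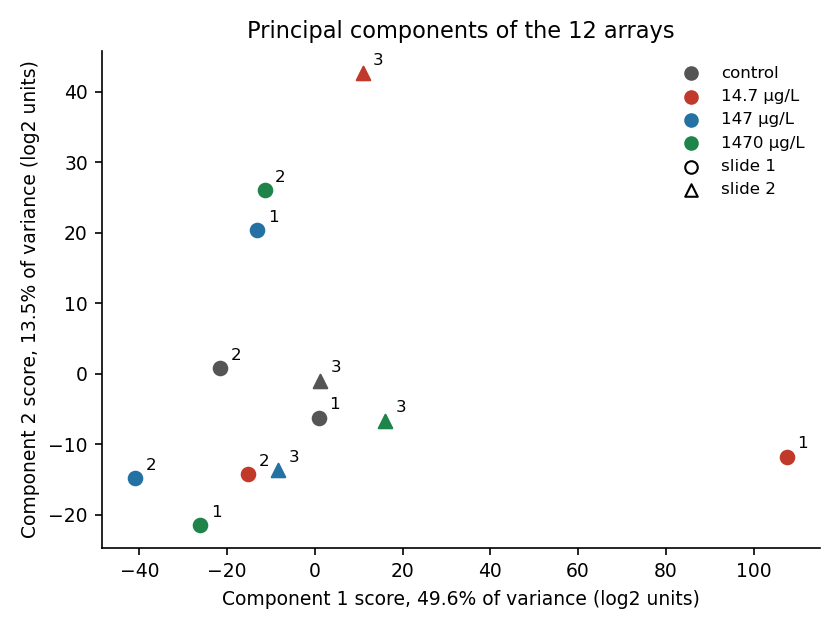
Scores of the 12 arrays on the first principal components of the tested probes (log2 units), coloured by TBEP concentration, with the replicate number beside each point and the slide shown by its shape. Replicate 1 at 14.7 µg/L has a score of 107.6 on component 1, while the other arrays lie between -41.0 and 16.0.

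At 14.7 µg/L, 2 of 10040 probes were lower than in controls and 0 were higher (limma, adjusted p under 0.05). Probe DM09561P4 fell by 5.84 on the log2 scale (SE 0.582, 95% interval -7.12 to -4.55, n = 3 per group, adjusted p = 0.00987), a 57.1-fold difference. Its mean log2 signal relative to the array's 75th percentile was 2.33 ± 0.45 (SD, n = 3) in controls and -3.51 ± 1.40 (SD, n = 3) at this dose. Probe DM04828P3 fell by 7.68 (SE 0.959, 95% interval -9.80 to -5.56, adjusted p = 0.0411), from 3.28 ± 0.73 to -4.40 ± 2.26 (SD, n = 3). Both were lower on 3 of 3 exposed arrays than on any control array.

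DM09561P4 gave 1334, 1673 and 872 intensity units in the 3 control pools and 7.80, 62.0 and 13.9 at 14.7 µg/L. DM04828P3 gave 2524, 3969 and 1406 in controls and 2.69, 67.0 and 5.86 at this dose. At 14.7 µg/L DM09561P4 was well above background on 2 of the 3 arrays and DM04828P3 on 1 of the 3, so the folds rest partly on signals close to background. With normexp background correction the log2 differences were smaller, -3.59 for DM09561P4 (adjusted p = 0.000937) and -4.19 for DM04828P3 (adjusted p = 0.00822). On slide 1 the log2 differences from control were -5.97 for DM09561P4 and -7.77 for DM04828P3, and on slide 2, with 1 array per group, they were -5.56 and -7.50. With the slide as a block the adjusted p was 0.0249 for DM09561P4 and 0.0709 for DM04828P3.

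The call of DM09561P4 was kept in 19 of 23 alternative settings, with adjusted p between 0.000426 and 0.787, and that of DM04828P3 in 7 of 23, with adjusted p between 0.00101 and 0.988. Where the call was lost, the log2 difference lay between -5.97 and -5.62 for DM09561P4 and between -8.04 and -6.71 for DM04828P3. The filter for signal on all 12 arrays removed both probes and is not among the 23. Over the 12 fits that each left out 1 array, the number of called probes ranged from 0 to 5. It was 0 without control replicate 1 and also without control replicate 2, 5 without replicate 2 at 14.7 µg/L, 3 without replicate 3 at that dose, and 1 without any of the remaining 8 arrays. DM15066P2 and DM09251P1 had the smallest p among probes with higher values at this dose, with log2 differences of 0.77 (SE 0.156, adjusted p = 0.545) and 0.72 (SE 0.178, adjusted p = 0.997), and neither passed.

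**Figure D2:**
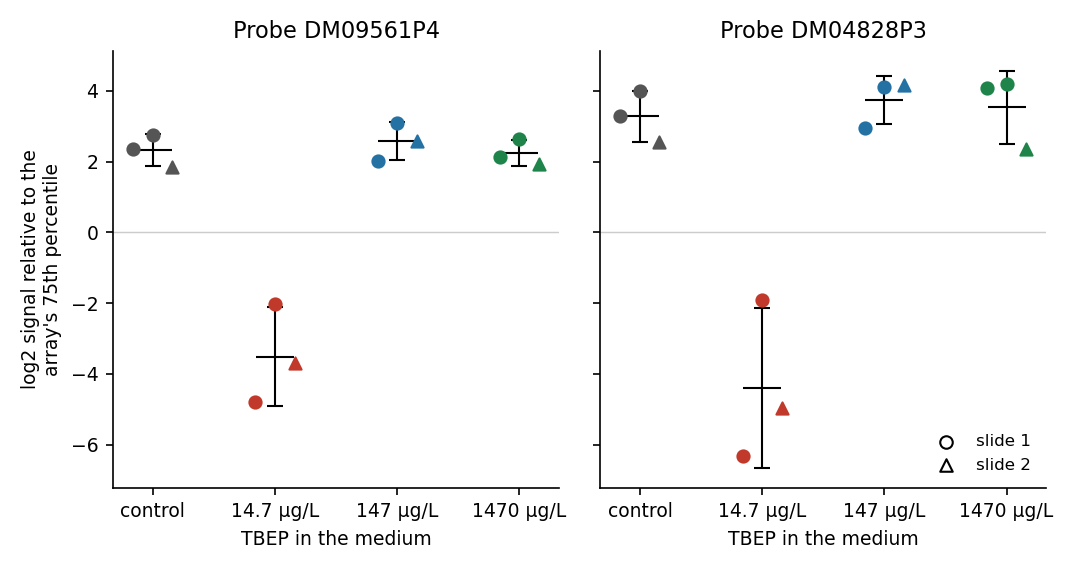
Log2 signal of probes DM09561P4 and DM04828P3 relative to the array's 75th percentile, by TBEP concentration. Points are single arrays (shape, slide), horizontal bars the group means and error bars the SD (n = 3); the group means at 14.7 µg/L are -3.51 and -4.40, and all other group means lie between 2.23 and 3.74.

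At 147 µg/L no probe passed the threshold against control. limma called 0 of 10040 probes, with 213 at an unadjusted p under 0.05 (88 higher, 125 lower), where 502 would be expected from uniform p-values. The highest-ranked probe was DM11927P1, whose log2 signal was 2.98 ± 0.25 at this dose and 1.54 ± 0.33 in controls (SD, n = 3). The difference of 1.44 (SE 0.220, 95% interval 0.96 to 1.93) had an adjusted p of 0.493. DM09143P1 differed by 1.29 (SE 0.230, adjusted p = 0.928). Among lower probes, DM10586P4 differed by -1.04 (SE 0.227, adjusted p = 1.00), with 2 of 3 exposed arrays well above background. DM04870P2 was well above background on 3 of 3 control arrays and on 0 of 3 arrays at 147 µg/L, an at least 2.00-fold lower value (adjusted p = 1.00). With normexp background correction its difference had the opposite sign, 0.0993, and those of DM10586P4 and DM09143P1 were -0.09 and 0.83.

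At 1470 µg/L, the highest concentration, no probe passed either. limma called 0 of 10040 probes, with 72 at an unadjusted p under 0.05 (16 higher, 56 lower), and the smallest adjusted p was 0.9999. The probes with the smallest p differed by less than 2-fold: DM07418P3 by 0.70 (SE 0.201) and DM01498P1 by 0.64 (SE 0.200) upward, and DM09625P1 by -0.59 (SE 0.168) and DM11327P1 by -0.95 (SE 0.276) downward on the log2 scale. With normexp the difference of DM09625P1 was -0.06. The 95% interval of a difference reached a median of 0.56 log2 units, or 1.48-fold, to either side. It lay wholly within 2-fold for 7582 probes (75.5%) at this dose, 7180 (71.5%) at 147 µg/L and 7250 (72.2%) at 14.7 µg/L. For the remaining probes a 2-fold difference was not excluded.

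No probe passed the test for a dose trend. The trend over the rank of the concentration gave 0 of 10040 probes past the threshold (limma), with 125 at an unadjusted p under 0.05 (28 rising, 97 falling). The probes ranked first were those just named for 1470 µg/L, and their slopes per dose step were 0.26 (SE 0.0647) for DM07418P3, 0.25 (SE 0.0727) for DM01498P1, -0.19 (SE 0.0488) for DM09625P1 and -0.31 (SE 0.0827) for DM11327P1, and -0.05 for DM09625P1 with normexp. A slope on the concentration itself gave 0 probes with 82 at an unadjusted p under 0.05, and a slope on log10 of the concentration plus 1 gave 0 with 114. The F test over the 4 groups called 2 probes, DM09561P4 (adjusted p = 0.0134) and DM04828P3 (adjusted p = 0.0477), with 214 at an unadjusted p under 0.05. Its count was 0 without control replicate 1, without replicate 3 at 147 µg/L and without replicate 1 at 1470 µg/L, 3 without replicate 2 at 14.7 µg/L, and 1 without any of the remaining 8 arrays.

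Against the lowest dose, the higher doses differed in the same 2 probes. Their means were 2.57 and 3.74 at 147 µg/L and 2.23 and 3.54 at 1470 µg/L, beside 2.33 and 3.28 in controls, for DM09561P4 and DM04828P3. DM09561P4 was higher by 6.08 on the log2 scale at 147 µg/L (SE 0.582, adjusted p = 0.00663) and by 5.75 at 1470 µg/L (SE 0.582, adjusted p = 0.0115) than at 14.7 µg/L. DM04828P3 was higher by 8.14 (SE 0.959, adjusted p = 0.0239) and 7.94 (SE 0.959, adjusted p = 0.0302). With normexp these differences were 3.76 and 3.50 for DM09561P4 and 4.55 and 4.39 for DM04828P3. No probe was called lower in these comparisons, and 704 and 259 probes had an unadjusted p under 0.05. Between 1470 and 147 µg/L limma called 0 probes, with 71 at an unadjusted p under 0.05. The count between 147 and 14.7 µg/L was 0 without replicate 2 at 147 µg/L, 8 and 5 without replicates 2 and 3 at 14.7 µg/L, and 1 without any single control, replicate 1 at 14.7 µg/L or replicate 1 at 147 µg/L. The count between 1470 and 14.7 µg/L went to 0 without replicate 3 at 14.7 µg/L or any single replicate at 1470 µg/L, to 6 without replicate 2 at 14.7 µg/L, and to 1 without any of the remaining 7 arrays.

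**Figure D3:**
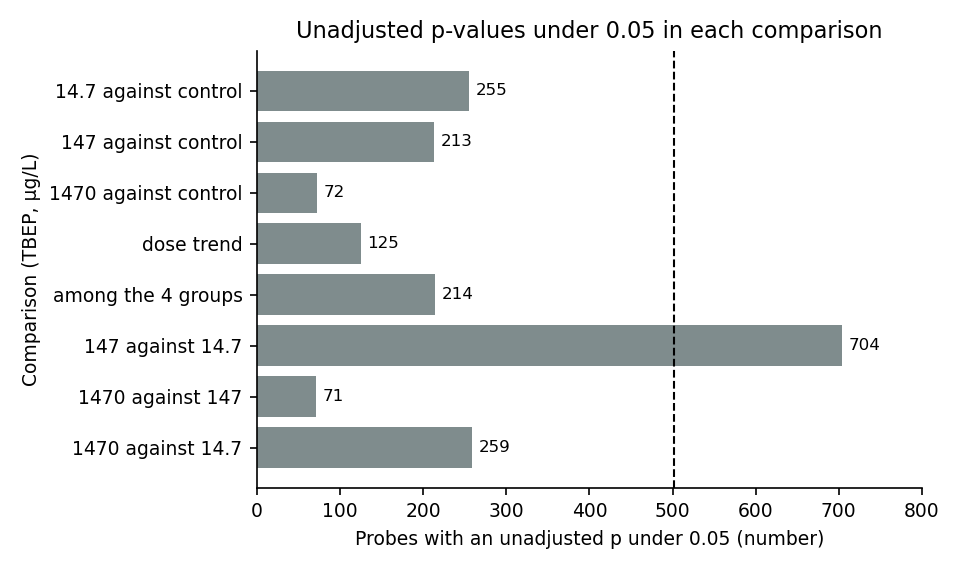
Number of probes with an unadjusted p under 0.05 in each comparison, out of 10040 tested (bars, counts beside them); the dashed line marks the 502 expected from uniform p-values. Of the counts drawn, that of 147 with 14.7 µg/L, 704 probes, exceeds the line. With normexp the counts at 14.7 µg/L and for 1470 with 14.7 µg/L (3198 and 2320) exceed it too, as do those without replicate 2 at 14.7 µg/L (1152 and 930). Without replicate 1 at 14.7 µg/L (365) or replicate 2 at 147 µg/L (261), the count of 147 with 14.7 µg/L is under 502.

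The doses share their control arrays, which alone makes their differences from control correlate. Across probes, the log2 differences at 147 and 1470 µg/L correlated with r = 0.544, where unchanged groups simulated against the same controls gave 0.378. The covariance was 0.0428 against a simulated 0.0411, a difference of 0.00166. In this simulation shared controls alone thus gave nearly as large a covariance, so the higher r does not show that these doses changed probes alike. For 14.7 with 147 µg/L r was -0.0885 (simulated 0.257) and for 14.7 with 1470 µg/L it was 0.196 (simulated 0.244), with covariances of -0.0137 and 0.0235 against simulated values of 0.0408 and 0.0404. Without replicate 1 at 14.7 µg/L these r were 0.269 and 0.252, with covariances of 0.0292 and 0.0212. Those covariances lie below the simulated values, so the simulation may overstate what shared controls give, and the excess of 0.00166 is uncertain. With 3 control arrays the controls could not be split into parts of at least 2 arrays each, and part of the excess of 0.00166 may also come from the shared controls.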

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

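The tests of the dose and of the odd array, both slide tests, and the test of the spread were chosen after the results they address had been seen. Groups of 3 arrays are too small for an outlier test.

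The low signal of DM09561P4 and DM04828P3 at 14.7 µg/L differed from the higher doses by tests of the difference itself. DM09561P4 was higher by 6.08 (log2) at 147 µg/L and by 5.75 at 1470 µg/L than at 14.7 µg/L (limma, adjusted p = 0.00663 and 0.0115), and DM04828P3 by 8.14 and 7.94 (adjusted p = 0.0239 and 0.0302). The calls of DM09561P4 held in 20 and 17 of 23 alternatives and those of DM04828P3 in 12 and 8 of 23, so the difference rests on less for DM04828P3. Where a call was lost, the log2 difference of DM09561P4 from 14.7 µg/L lay between 5.815 and 6.08 at 147 µg/L and between 5.54 and 5.904 at 1470 µg/L. For DM04828P3 it lay between 7.175 and 8.54 and between 6.97 and 8.534. The 6 arrays of a comparison divide into 10 splits, too few for a share under 0.05. At 14.7 µg/L against control, 1 of the 10 splits, the real one, gave 2 probes or more, and the highest other gave 0. For 147 against 14.7 µg/L it was also 1 of 10 (real 2, highest other 0), and for 1470 against 14.7 µg/L 1 of 10 (real 2, highest other 1). For the F test, 1 of 100 drawn splits of the 12 arrays, the real one, gave 2 probes, and the highest other gave 0, so a chance division of the arrays was excluded at 0.05 for that count.

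Over all probes, 5 were at least 2-fold lower on each array at 14.7 µg/L than on every array of the other groups: DM09561P4, DM04828P3, DM04036P4, DM10404P2 and DM09930P1. The last 3 did not pass against control: DM04036P4 and DM10404P2 differed by log2 -6.08 and -3.92 (adjusted p = 0.183 and 0.114), and DM09930P1, well above background on 0 of 3 arrays at 14.7 µg/L, was at least 7.32-fold lower (adjusted p = 0.114). Of the 220 choices of 3 arrays, 2 gave 5 or more such probes, which argues against any 3 arrays doing so, although control replicate 2, 147 µg/L replicate 2 and 1470 µg/L replicate 1, all on slide 1 and of different groups, gave 19. A difference between slides was examined over the 112 choices of 2 arrays on slide 1 and 1 on slide 2. Of these, 1, the real one, gave 6 probes at least 2-fold below the rest of their own slide on both slides, and the highest other gave 2. The 5 probes meet this limit by their selection, so the count cannot decide on a difference between slides. Slide and group were balanced, so a difference common to all arrays of a slide would not single out 1 dose. The odd array of 14.7 µg/L replicate 1 alone does not make the signals of replicates 2 and 3 low, but the probes were chosen for being low there, and low values that fell together by chance beside the odd array were not excluded for the set: without it 3 of the 55 pairs of the other 11 arrays gave as many low probes as the remaining pair of the dose (real 5, highest other 13). For DM09561P4 the odd array is argued against as the whole cause, since limma over all probes still called it without that array (log2 -5.19, adjusted p = 0.0118, 0.000426 to 0.787 over its alternatives), while DM04828P3 was not called (log2 -6.71, adjusted p = 0.0930, 0.00101 to 0.988). An effect of the lowest dose that is absent at higher doses, a shared vessel or clutch, or a sequence variant under the probes may also account for them, and none of these was tested.

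The array of 14.7 µg/L replicate 1 had 332 probes at least 8-fold below their median on the other arrays, against 0 to 23 on each other array, and 3 at least 8-fold above. These probes held 0.212% of the signal there and 4.67% to 14.4% on the other arrays, and 180 of them were not well above background there. Of the 12 low probes printed at 2 spots, 100% were 4-fold or more low at both. They were chosen by the mean of their spots at the stricter 8-fold limit, which nearly fixes this outcome. It therefore cannot decide on a local flaw on the slide. Failed labelling or hybridisation is argued against by the 10 spike-in probes, whose median log2 difference from the other arrays was 0.05. Of the equally bright probes, 88.1% lay within 2-fold of the other arrays, so most were not low relative to their array. These values were set relative to each array's own signal level, which removes a loss common to all probes. They therefore cannot decide on a general loss of RNA. Before that scaling the median intensity was 32.2 on this array and between 27.0 and 42.1 on the other arrays. The 14.7 µg/L dose is argued against by its other replicates. Their medians for the low probes were -0.82 and 0.12 relative to the other groups. The state of the animals in this pool may differ, but no value here tests it.

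With the processed signals of all 12 arrays, unadjusted p-values under 0.05 were fewer than the 502 that uniform p-values give in each comparison except 147 against 14.7 µg/L. This depended on the processing and on single arrays. With normexp there were 3198 at 14.7 µg/L, 2320 for 1470 against 14.7 µg/L and 981 in the F test. Normexp also moved the median log2 difference of all probes at 14.7 µg/L, from 0.033 to 0.206. Whether that shift raised these counts was not tested. Without replicate 2 at 14.7 µg/L the same counts were 1152, 930 and 685. The 704 of 147 against 14.7 µg/L fell to 365 without replicate 1 at 14.7 µg/L. It fell to 261 without replicate 2 at 147 µg/L, and lay between 577 and 1832 without any other single array. At 1470 µg/L a spread inflated by 14.7 µg/L replicate 1 is argued against as the whole cause, since without that array 0.847% of the probes had an unadjusted p under 0.05. A difference between slides is argued against likewise, with 0.707% when the slide was a block. A part played by the shared spread was not excluded. With array weights the counts were 461 at 147 µg/L and 153 at 1470 µg/L, and with each pair of groups fitted alone 382 and 147. At 14.7 µg/L these settings lowered the count, to 178 and 168. Other splits often gave more such probes than the real groups. As large a count came from 7 of 10 splits at 14.7 µg/L (real 255, highest other 862), 6 of 10 at 147 µg/L (213, 470) and 8 of 10 at 1470 µg/L (72, 484). Between doses it came from 4 of 10 for 147 against 14.7 (704, 1912), 9 of 10 for 1470 against 147 (71, 1001) and 8 of 10 for 1470 against 14.7 (259, 1861). The highest others at 14.7 µg/L against control and in the 3 comparisons between doses lay above 502. Each is the largest of several splits, and probes are not independent, so these counts alone do not show a structure of the arrays that crosses the groups. The source of the high counts was not tested. Those at 147 and 1470 µg/L against control lie below 502.

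A real count of 0 calls is reached by any split, so the splits say nothing about it: 10 of 10 at 147 µg/L, at 1470 µg/L and between these doses (highest other 0), and 100 of 100 drawn splits for the trend (highest other 7). Chance was not excluded for the 125 probes of the trend at an unadjusted p under 0.05, which 88 of 100 drawn splits reached (highest other 2157), nor for the 214 of the F test, which 76 of 100 reached (highest other 1463).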

How the results depend on the processing

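The group permutation test, its alternatives and the counts of low probes on 1 array were chosen after seeing the data. In all alternatives that kept the adjusted threshold, limma called 0 probes at 147 and 1470 µg/L, for the trend, and between these doses. Normexp, quantile and median normalization, array weights and the deposited log2 values kept the other counts within 1.5 times. Normexp moved the median log2 difference of all probes by 0.173 at 14.7 µg/L and by 0.122 at 147 µg/L, and no other normalization moved it by over 0.1.

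The counts of 2 at 14.7 µg/L against control, in the F test, for 147 against 14.7 and for 1470 against 14.7 µg/L depended on several choices. The filter for signal on all 12 arrays removed both probes and gave 0, 0, 0 and 0. Slide 1 alone, with fewer arrays, gave 0, 0, 0 and 0. Each pair of groups fitted alone gave 0, 0 and 0. An intensity trend with robust moderation gave 1, 1, 1 and 1 (the cause was not tested). Without a filter on dim probes, with more probes tested, the first 2 counts were 1 and 1. The slide as a block gave 1, 1, 2 and 1 (the cause was not tested). Leaving out 1 array gave 0 to 5, 0 to 3, 0 to 8 and 0 to 6.

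With the replicate number as a block the counts were 3, 4, 8 and 5. Over the 18 pairs of arrays that share a number, the deviations from the group means correlated above 0.1 in 8, with a lowest r of -0.369. Their median r was 0.039, higher than the -0.148 of pairs with different numbers, so some pairing was not excluded. Since 5 of 12 arrays correlated best with their own number, the numbers were not taken to pair the samples.

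An unadjusted p under 0.05 with a 1.5-fold minimum gave 155, 129 and 45 probes at the rising doses, 65 for the trend (fold over the whole dose range, 3 probes with the fold per dose step), 159 in the F test (largest difference from control, 7 higher and 46 lower with the mean difference of the 3 doses), and 462, 41 and 185 for 147 against 14.7, 1470 against 147 and 1470 against 14.7 µg/L, since it does not correct for the number of probes. The 147 µg/L difference of DM04870P2, a probe close to background, turned to 0.0993 with normexp (adjusted p = 0.906, 0.174 to 1.00 over its alternatives; the cause was not tested). The 332 low probes of 14.7 µg/L replicate 1 became 135 with normexp, and 151 with the filter on all arrays, which removes probes lost on 1 array. Normexp raises dim signals but also used the median in place of the processed signal, and these changes were not tested apart. The group permutation p stayed between 0.065 and 0.915 in all alternatives. Signal over background limits the folds of probes that were lost. Gene list tests and alternatives for named genes were not run, because no probe could be tied to a gene.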

Other observations

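Some probes ranged widely between pools. Without replicate 1 at 14.7 µg/L, 102 probes ranged over more than 16-fold between the remaining arrays and 22 over more than 64-fold, among them 5 and 3 of the probes that were low on all 3 arrays at 14.7 µg/L. The probes named here were chosen after their values were seen. DM15080P2 had an intensity of 38590 on replicate 3 at 14.7 µg/L and between 13.6 and 29.2 on the other 11 arrays. DM07108P3 had 26.9 on replicate 1 at 1470 µg/L and 55150 and 61800 on the other replicates of that dose.

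A set of 19 probes, DM07108P3 among them, was at least 2-fold lower on control replicate 2, 147 µg/L replicate 2 and 1470 µg/L replicate 1 than on each of the other 9 arrays. The mean log2 difference of these 3 arrays from the other 9 had a median of -2.89 over the set and ranged from -5.59 to -2.51. None of the 19 probes belonged to the low set of replicate 1 at 14.7 µg/L. The 3 arrays come from 3 groups, so this variation did not follow the dose.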
